A study of Mus musculus with 9 samples.

How the data were processed

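Polyadenylated RNA of naive CD4+ T cells from lymph nodes of wild-type C57BL6/J mice was sequenced in 9 libraries, 3 each of freshly isolated cells, cells cultured for 20 h without IL-1b and cells cultured for 20 h with recombinant IL-1b at 10 ng/mL. Per the labels' protocols, RNA was extracted with RNAiso Plus, cleaned on a column and made into libraries with the NEBNext Ultra II Directional kit. Per the submitters' processing notes, reads were aligned with STAR and quantified with RSEM on mm10; their versions are not given in the sources used here, nor is the RSEM strand setting, so reads of overlapping antisense genes may not be separated. The deposited tables, per the file headers, give for each gene the RSEM expected counts, which share reads among matching genes and are not normalised. They also give the TPM values of each gene, deposited as RSEM made them from expected counts and effective lengths, and FPKM values, deposited alike, which were not used here. Gene and effective lengths in bases are those of the deposited tables, per the file headers. The labels do not say whether replicates come from separate animals or cultures, so p-values may measure only technical spread.

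Of 55487 gene identifiers 55141 (99.38%) matched a GENCODE M21 symbol, whose assembly GRCm38 is the same as mm10, and unmatched identifiers were kept in library totals and tests. GC content was taken for 55164 genes as the mean over their GENCODE M21 transcripts. Expected counts were rounded to whole numbers. Library totals ranged from 13518814 to 23056686, so that a floor of 3 counts in a library equals 0.130 to 0.222 CPM. Fresh, cultured and IL-1b-treated libraries held on average 17336, 17287 and 16273 genes above 0, and 17067 ± 79.7, 17061 ± 56.0 and 16087 ± 47.4 (SD, n = 3) at an equal depth of 13518814 counts. The median effective length behind a count was 2405, 2135 and 1794 bases, the share of mitochondrial counts 2.02, 2.49 and 3.21%, and the share of the 100 most counted genes 19.6, 22.7 and 26.9%, led by Eef1a1. Replicates differed beyond counting error, with a chi-square of 2.97 to 5.76 per gene between pairs of libraries with at least 20 counts.

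Differences between groups were tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test over all 9 libraries in 1 fit with the group as the only term, Benjamini-Hochberg adjustment, threshold 0.05). This left 13043 genes with a biological coefficient of variation of 0.0665. Gene lists, 37 in number and 8 of them markers of other cell types, were written from general knowledge; 34 had at least 3 tested members and were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01, an estimated correlation beside it and fry as an alternative. The 3 lists of stromal, CD8 and erythroid markers had fewer, and the 81 tested ribosomal protein genes were no fixed list. The groups, comparisons, tests, lists and most alternative settings, and the rule for naming genes, were set before the data were examined. By that rule the text names the 10 genes with the largest changes up and down between IL-1b-treated and cultured and between cultured and fresh cells, and 5 each way between IL-1b-treated and fresh cells, among called genes with a symbol other than a Gm or Rik model name, a mean of at least 1 TPM in 1 group and separate replicates, with list members of smallest adjusted p and a fixed panel of 23 genes, of which some genes are not reported here. Medians on the TPM scale are of group means of log2(TPM + 0.5). Genes with 0 counts in a group are given as bounds against 3 counts over the group, and genes with 1 to 3 counts as ratios with exact 95% intervals. Stat6, Il6ra, Cdt1 and Vsir are named below because their direction changed with the processing.

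The alternative settings set then were other scalings (RLE size factors, upper quartile, library size alone), other filters, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), an effective length offset, fits of only the groups compared, a replicate block, a threshold of 1 on the absolute log2 fold change, removal of genes with shared reads, and leaving out each library. Removing each library's trend on GC content and length with mgcv 1.9.3, leaving out the 100 most counted genes and summing markers in CPM were chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the tables and drew the figures.

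The scripts were tested on simulated data with 200 genes changed by 1.2, 1.5, 2 or 4-fold. Of the changed genes in each class, 30, 74, 65.3 and 83.7% were recovered for IL-1b-treated against cultured cells (12766 genes tested), 16, 56, 74 and 89.6% for cultured against fresh (12761), and 28, 75.5, 78 and 94% for IL-1b-treated against fresh (12773), and 8, 15 and 16 unchanged genes were called. With an imposed trend on GC content and length, 3202, 3295 and 3244 unchanged genes were called, and 17, 17 and 10 after the trend was removed. The 2 lists changed in the simulations were recovered in each comparison, with 0 to 3 other lists called.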

Results

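Naive CD4+ T cells, the helper lineage before its encounter with antigen, were taken from the lymph nodes of wild-type C57BL6/J mice, and their polyadenylated RNA was sequenced. The 9 libraries form 3 groups of 3, which are freshly isolated cells (fresh), cells cultured for 20 h without interleukin-1 beta (cultured) and cells cultured for 20 h with recombinant IL-1b at 10 ng/mL (IL-1b-treated). IL-1b is an inflammatory cytokine that acts through the receptor Il1r1 and its partner Il1rap, and NF-kB is the textbook end of that pathway. Total counts per library were 23056686, 15958080 and 13518814 for fresh cells, 15127261, 15953937 and 15842040 for cultured cells, and 17822120, 14864468 and 15923777 for IL-1b-treated cells. The first principal component held 62.3% of the variance and the second 8.77%. On the third, with 6.37%, IL-1b-treated replicate 3 stood apart at 39.6, against -14.0 and -19.8 for replicates 1 and 2. Log2 CPM values of replicate libraries correlated across genes with r from 0.979 to 0.986, where genes are not independent replicates. Below, ± gives the SE of a log2 fold change and otherwise the SD over n = 3 libraries, gene levels are TMM-normalised CPM (counts scaled to the effective library total), and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

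**Figure D1:**
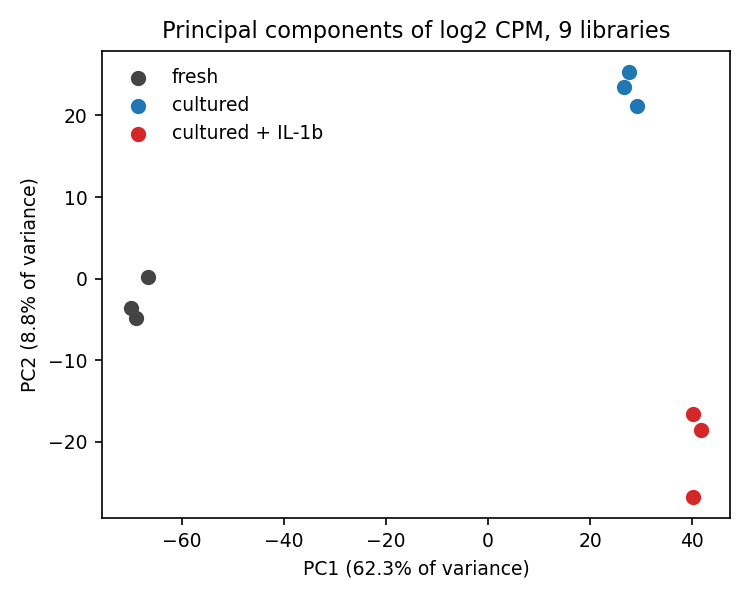
Each point is 1 of the 9 libraries on the first 2 principal components of log2 CPM, coloured by group. The horizontal axis, with 62.3% of the variance, parts fresh from both cultured groups, and the vertical axis, with 8.77%, parts cultured from IL-1b-treated libraries.

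The comparison of IL-1b-treated with cultured cells asks what the cytokine changed during the same 20 h of culture. IL-1b-treated cells had more messenger RNA for ribosomal proteins and, relative to the median gene, for the respiratory chain, whose median was -0.06 on the TPM scale, and less of several structured RNAs that lack a poly(A) tail, which were near the level of fresh cells in IL-1b-treated cells and higher in cultured cells. Since polyadenylated RNA was sequenced, counts of RNAs without a tail may follow the library preparation rather than the cytokine, which was not tested. The receptor gene Il1r1 had 0 counts in all 9 libraries, and the NF-kB target genes did not move as a group. Most differences were under 2-fold and followed transcript length, with short transcripts higher and long ones lower.

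Of 13043 genes tested, 3768 differed at an adjusted p threshold of 0.05, of which 2037 rose and 1731 fell. The median fold of these genes was 1.24, and 34 rose and 82 fell by at least 2-fold. In TPM values the 3 IL-1b-treated libraries lay entirely above or below the 3 cultured ones for 6359 genes, or 48.8%, where chance gives 10%. The median gene was lower with IL-1b on the TPM scale, and such a shift can itself separate replicates. The split of directions depended on how the libraries were scaled. Scaling by library size alone moved the median of all genes to -0.12 on the log2 scale and gave 1191 higher and 3273 lower genes, and log2(TPM + 1) values gave 289 higher and 4452 lower with a median of -0.25. On the TPM scale referred to below, log2(TPM + 0.5), the median of all genes was -0.28. Directions below are relative to the median gene, and 27 of the 3768 genes had the other sign under library size scaling and 808 on the TPM scale. Genes with an effective length of 13.17 to 678.8 bases had a median log2 fold change of 0.35, with 472 higher and 15 lower, while those of 4618 to 123000 bases had a median of -0.17, with 31 higher and 525 lower. With the trend on GC content and length removed from each library, 2424 genes differed, 1853 higher and 571 lower, and 1983 of the 3768 kept their call and direction.

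**Figure D2:**
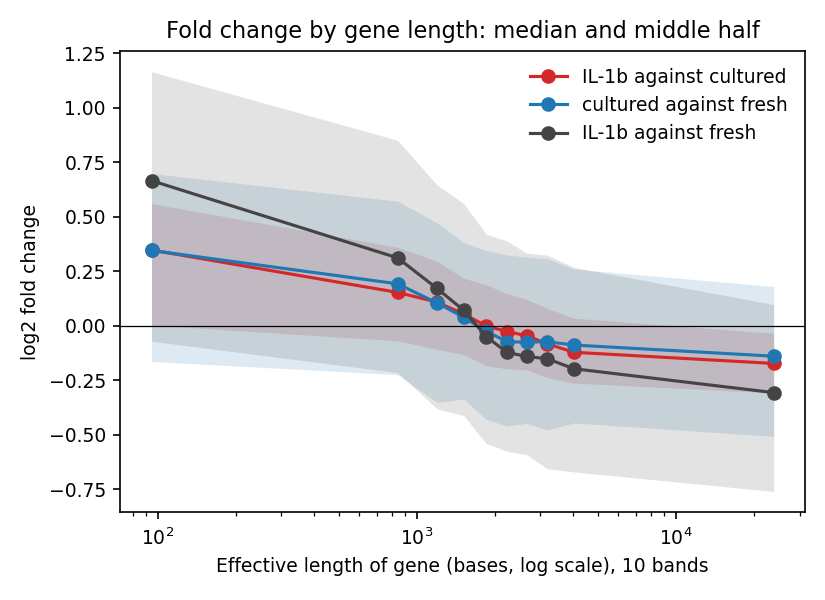
The vertical axis gives the log2 fold change under TMM scaling and the horizontal axis the effective length in bases, on a log scale, in 10 bands of genes, with a line of band medians for each comparison, a shaded range from the lower to the upper quartile, and each point at the geometric middle of its band's limits. For IL-1b-treated against cultured cells the medians run from 0.35 in the shortest genes to -0.17 in the longest.

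Among the named genes, apart from the weakly expressed ones given last, the largest decreases were in small structured RNAs and at Lars2. Rn7s2, 1 of the near-identical loci of the 7SL RNA of the signal recognition particle, fell from 68.7 to 6.88 CPM, against 7.86 CPM in fresh cells (log2 fold change -3.32 ± 0.21, adjusted p = 5.41e-11). Rmrp and Rpph1, the RNA parts of ribonucleases MRP and P, fell by 3.19 and 2.94 on the log2 scale, and Rn7sk, which holds the elongation factor P-TEFb inactive, fell by 1.97. None of these 4 RNAs was called between IL-1b-treated and fresh cells with edgeR. The 7SL and 7SK loci together took 0.0127% of counts in cultured, 0.0018% in IL-1b-treated and 0.0022% in fresh libraries. Lars2, the mitochondrial leucyl-tRNA synthetase gene, fell from 380 ± 8.91 to 63.6 ± 3.81 CPM, against 121 ± 4.40 CPM in fresh cells (-2.58 ± 0.05, adjusted p = 5.76e-21). Lars2 shares sequence with ribosomal RNA, so its counts may not be those of the enzyme's messenger. Loci resembling ribosomal RNA, Lars2 among them, took 0.486 ± 0.0131% of counts in cultured, 0.102 ± 0.0011% in IL-1b-treated and 0.161 ± 0.0019% in fresh libraries. Reads of RNAs without a poly(A) tail in libraries of polyadenylated RNA may depend on how each group's libraries were prepared. Whether these falls follow the preparation or the cells cannot be told from groups that each hold their own libraries. The other genes among these largest decreases were weakly expressed: the myomesin gene Myom1 changed by -2.88 and the myosin gene Myh10 by -1.73. The Fanconi anaemia gene Fanca changed by -1.68, the chromatin gene Phf21b by -1.59 and the MHC class II gene H2-Eb1 by -1.49. The Myh10 call was lost when any of 5 libraries was left out, with adjusted p up to 0.0969.

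The largest increases included the inducible chaperone Hspa1b (1.63 ± 0.28, adjusted p = 9.87e-05), which stayed low at 2.57 ± 0.77 against 0.82 ± 0.41 CPM and shares reads with Hspa1a. The mitochondrial cytochrome oxidase messenger mt-Co3 rose from 576 ± 68.8 to 1350 ± 114 CPM (1.23 ± 0.10, adjusted p = 2.04e-09), and reads of nuclear copies of mitochondrial DNA may fall on such genes. Coa6, a cytochrome oxidase assembly factor, rose by 0.95, the RNA exosome gene Exosc6, which shares reads with other loci, by 1.01, the small nuclear protein gene Ss18l2 by 1.00 and the histone gene Hist1h2ap, 1 of a family of similar sequence, by 1.26. The ribosomal protein pseudogenes Rpl17-ps8 and Rps15a-ps7 rose by 1.01 and 0.92, where their parent genes may share reads, and the T cell receptor segment Trav7d-4 and the receptor Cd200r3 by 1.52 and 1.16. The call was lost for Trav7d-4, Cd200r3, Rpl17-ps8 and Rps15a-ps7 when 7, 6, 3 and 3 of the 9 libraries in turn were left out, with adjusted p up to 0.254, 0.148, 0.121 and 0.0936, and for Exosc6 without IL-1b-treated replicate 3 (0.0527).

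Of 81 ribosomal protein genes 80 rose and none fell (median log2 fold change 0.59), and the median stayed above 0 at 0.47 with library size scaling and 0.26 on the TPM scale, and was 0.37 with the GC and length trend removed. These genes took 16.0 ± 0.182% of counts in IL-1b-treated, 11.8 ± 0.0708% in cultured and 8.44 ± 0.124% in fresh cells. Among gene lists fixed beforehand, 4 of 34 were called by camera with its preset correlation, all upward. Of 13 mitochondrially encoded messengers 12 rose and none fell (median 0.46, camera adjusted p = 7.58e-16), among them mt-Co1 and mt-Nd1, and the median was 0.10 on the TPM scale. Adjusted over the list alone, all 13 rose, and the list's adjusted p was 0.115 with an estimated correlation. Nuclear-encoded respiratory chain genes rose in 26 of 37 cases and none fell (median 0.28, adjusted p = 2.67e-12), and their median was -0.06 on the TPM scale, above that of all genes. Their adjusted p was 0.00458 with an estimated correlation, and adjusted over the list alone 29 rose and 1 fell. Uqcrc2 of complex III rose from 162 to 230 CPM, and Atp5c1, Ndufa9 and Cox6c rose by 0.50, 0.53 and 0.51.

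Ribosome assembly genes rose in 14 and fell in 2 of 32 cases (median 0.16, or -0.24 on the TPM scale; adjusted p = 0.00355, and 0.115 with an estimated correlation). Adjusted over the list alone, 15 rose and 3 fell. The nucleolar chaperone Npm1 rose from 1025 to 1547 CPM (0.59 ± 0.03, adjusted p = 1.09e-12), and Nhp2 of box H/ACA particles by 0.66, while Polr1a, the largest RNA polymerase I subunit, fell by 0.31. Heat shock genes rose in 10 and fell in 1 of 16 cases (median 0.18, or -0.08 on the TPM scale), with the same counts adjusted over the list alone. Their camera adjusted p was 0.00436, and 0.231 with an estimated correlation. Hspa8 rose from 2650 to 3358 CPM, Hsp90aa1 by 0.44 and Hspe1 by 0.54. With the GC and length trend removed, glycolysis, endoplasmic reticulum chaperone and T cell receptor complex lists were called as well, at adjusted p = 0.0127, 0.0193 and 0.0176, which were 0.142, 0.142 and 0.210 with an estimated correlation.

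Textbook NF-kB targets rose in 3 and fell in 4 of 28 cases (median -0.09, adjusted p = 0.613), and 2 rose and 4 fell adjusted over the list alone. Nfkbia, the inhibitor that NF-kB itself induces, rose by 0.17 ± 0.05 (adjusted p = 0.0213) with TMM scaling and had the other sign on the TPM scale, and its adjusted p was 0.145 without cultured replicate 1 and 0.0970 without IL-1b-treated replicate 1. The ubiquitin editor Tnfaip3 was not called at 0.04 (adjusted p = 0.753), and Nfkb1 fell by 0.25. Of 21 genes of the IL-1 receptor family and its adaptors none rose and 3 fell (adjusted p = 0.437), including the kinase gene Ikbkb by 0.28 and the inhibitory kinase gene Irak3 by 0.45, a call lost without any of 8 libraries (adjusted p up to 0.183). The 0 counts of Il1r1 (ENSMUSG00000026072, mm10 chromosome 1, 40225080 to 40317257) allow at most 0.130 to 0.222 CPM per library. Its partner Il1rap was not called at 0.09 (adjusted p = 0.687), nor was Il18r1 at 0.14. The decoy receptor gene Il1r2 had 4 counts in cultured, 1 in IL-1b-treated and 0 in fresh cells, and the antagonist gene Il1rn had 1, 0 and 3.

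**Figure D3:**
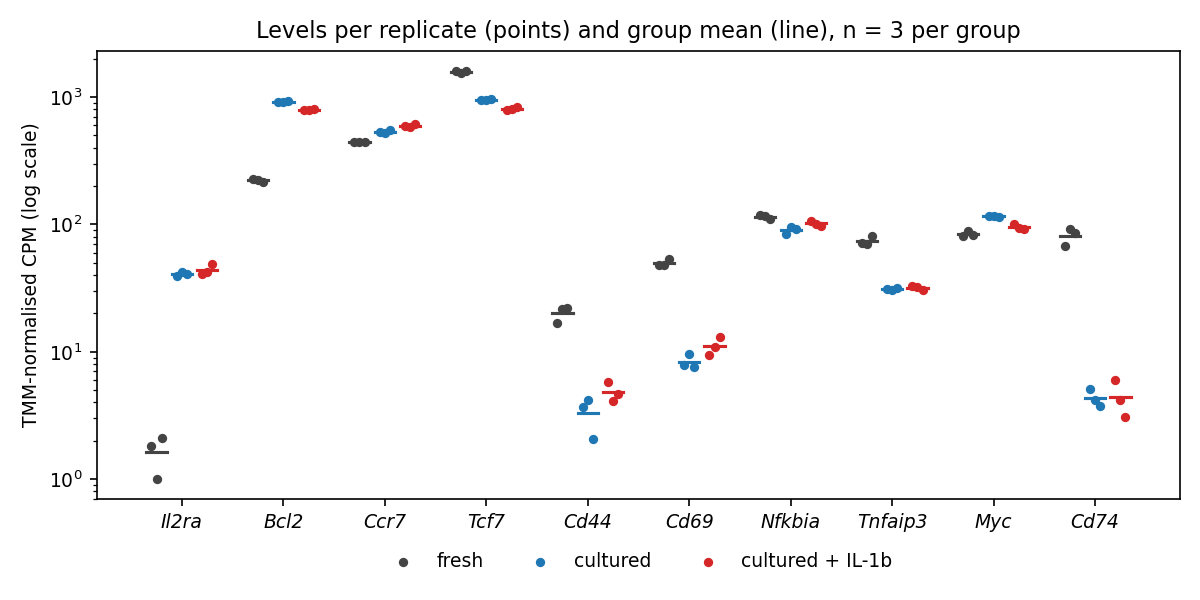
Points are single libraries, 3 per group, and short lines are group means of TMM-normalised CPM, on a log scale, for 10 genes. Bcl2 stood at 223 ± 5.94 CPM in fresh and 923 ± 12.3 in cultured cells, and the rise of Ccr7 and Nfkbia with IL-1b has the other sign on the TPM scale.

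Lineage lists were not called. Th17 genes rose in 0 and fell in 1 of 8 tested cases, with the signal transducer Stat3 down by 0.34. Th1 genes rose in 1 and fell in 1 of 12 cases, where Stat4 rose by 0.36, and Cxcr3, a Th1 chemokine receptor, went from 25 counts to 3, a ratio of 7.97 with an exact 95% counting interval of 2.43 to 41.2, and its call was lost when any of 7 libraries was left out. Th2 genes rose in 0 and fell in 1 of 5 cases, or 2 and 0 with the GC and length trend removed, regulatory T cell genes in 2 and 1 of 13, and follicular helper genes in 3 and 1 of 10. Foxp3, Gata3, Bcl6 and the quiescence regulator Klf2 were not called at -0.19, -0.09, 0.04 and -0.08, though Klf2 was called without cultured replicate 2 (adjusted p = 0.0400). Naive T cell genes rose in 7 and fell in 11 of 26 cases (adjusted p = 0.613), or 8 and 3 with the GC and length trend removed, and Slfn2, which keeps T cells quiescent, rose from 930 to 1239 CPM. The lymph node homing gene Ccr7 rose by 0.16 with TMM scaling and had the other sign on the TPM scale, while the naive cell regulator Tcf7 fell from 953 to 807 CPM and the survival gene Bcl2 from 923 to 797, a call lost with the GC and length trend removed (adjusted p = 0.0545). Memory and effector genes rose in 5 and fell in 3 of 19 cases, or 9 and 4 adjusted over the list alone. The activation marker Cd44 was not called at 0.57 (adjusted p = 0.0617) but was called without cultured replicate 2 (0.0244) or IL-1b-treated replicate 2 (0.0435). Cd69 rose from 8.32 to 11.1 CPM, a call lost without cultured replicates 1 or 3 or IL-1b-treated replicate 3 (adjusted p up to 0.146), Il2ra was not called at 0.11, and Myc fell from 116 to 95.5 CPM. Proliferation genes rose in 2 and fell in 0 of 29 cases, with the replication clamp Pcna up from 169 to 257 CPM.

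Of the remaining lists, interferon response genes rose in 7 and fell in 3 of 41 cases, T cell receptor complex genes in 11 and 6 of 23 with Cd3d up from 380 to 524 CPM, endoplasmic reticulum chaperones in 9 and 3 of 19 (adjusted p = 0.0872, and 0.0373 without cultured replicate 2), glycolysis genes in 7 and 3 of 26, and sterol synthesis genes in 7 and 4 of 24. Activation genes rose in 2 and fell in 3 of 23 cases, survival genes in 2 and 6 of 12, pro-apoptotic genes in 2 and 0 of 17 (0 adjusted over the list alone), p53 targets in 4 and 0 of 20, and STAT5 targets in 1 and 4 of 16. The only STAT5 target that rose, Lta, lost its call without any of 7 libraries (adjusted p up to 0.187). ATF4 stress genes rose in 3 and fell in 2 of 19 cases, glucocorticoid response genes in 3 and 2 of 12, secreted cytokines in 3 and 1 of 13, homing receptors in 5 and 5 of 20 and inhibitory receptors in 3 and 0 of 9. Removing the GC and length trend changed these counts to 2 and 1 for survival genes, 0 and 0 for pro-apoptotic genes, 2 and 0 for STAT5 targets and 8 and 1 for homing receptors. They became 9 and 0 for glycolysis genes, 5 and 0 for sterol synthesis genes and 11 and 1 for T cell receptor complex genes. B cell markers rose in 2 and fell in 2 of 20 cases, and 1 of 11 myeloid markers rose, the cystatin Cst3 from 39.9 to 55.9 CPM. No neutrophil, NK, CD8, erythroid or gamma delta marker tested here was called with edgeR over all genes and libraries. Adjusted over the list alone, 1 CD8 marker rose and 1 erythroid marker fell. Cd8b1 was called without cultured replicate 2 (adjusted p = 0.0222).

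Setting cultured against fresh cells asks what 20 h without the cytokine changed. Cultured cells had less messenger RNA of immediate early, NF-kB target and interferon response genes, and more of sterol synthesis genes, of the survival gene Bcl2 and of the interleukin-2 receptor gene Il2ra. Each of the 20 B cell markers fell, and so did each of the 6 neutrophil markers that passed the filter, of 12 listed. Both list calls were lost with an estimated correlation (camera adjusted p = 0.197 and 0.315). Regulators of the naive state moved both ways, with Ccr7 up and Tcf7 and Foxo1 down.

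Of the 13043 genes, 7594 differed, 3829 higher and 3765 lower, with a median fold of 1.47, and 763 rose and 891 fell by at least 2-fold. Replicates of the groups were separate in TPM values for 60.4% of genes, where chance gives 10% and a shift of the median gene can add to it. The log2(TPM + 1) values gave 1877 higher and 4842 lower genes, with the median gene at -0.19, and the median gene was at -0.21 on the TPM scale, on which 554 of the 7594 had the other sign. With the GC and length trend removed, 7076 genes differed and 5879 of the 7594 kept their call and direction.

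Several genes had 0 to 3 counts in fresh cells and many after culture. Akr1c18, a steroid dehydrogenase gene, was at least 90.2-fold higher against a floor of 3 counts over the 3 fresh libraries, the adhesion gene Mpzl2 at least 64.3-fold and the glycosyltransferase gene Gbgt1 at least 12.4-fold. Where fresh cells had 1 to 3 counts, the ratio was 350 (exact 95% counting interval 62.3 to 13900) for Fsd1l, 193 (34.1 to 7660) for the kinase gene Dyrk4, 94.1 (16.4 to 3760) for Patl2 and 84.4 (28.5 to 412) for the laminin gene Lama5. These intervals and floors cover counting error only. The activin receptor gene Acvr1c rose from 0.0883 to 16.9 ± 1.66 CPM (7.43 ± 0.32, adjusted p = 3.28e-15), the microtubule gene Map6 from 0.391 to 40.1 ± 0.841 CPM and Exosc6 from 0.141 to 7.64 CPM. The heat-inducible chaperones Hspa1a and Hspa1b, which share reads, went from 257 ± 14.3 to 0.193 CPM (-10.35 ± 0.17, adjusted p = 1.32e-22) and from 705 ± 25.6 to 0.82 CPM (-9.73 ± 0.10, adjusted p = 4.27e-26). Against the floor, the immunoglobulin gene Igha was at least 77.5-fold lower after culture, the histone genes Hist1h4n and Hist2h2bb at least 77.8-fold and 19.2-fold, the neutrophil granule gene Ltf at least 38.8-fold and the cytokine gene Il1b itself at least 25-fold. Lenep, Krt80 and Apol9b were at least 30.7-fold, 28.4-fold and 18.9-fold lower.

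Activation and immediate early genes fell in 17 and rose in 3 of 23 cases (median -1.63, camera adjusted p = 1.07e-05, and 0.0312 with an estimated correlation). Jun fell from 179 to 5.69 CPM (-4.97 ± 0.10, adjusted p = 2.05e-21), Junb and Fos fell by 2.85 and 2.84, and Cd69 fell from 49.7 to 8.32 CPM, while Il2ra rose from 1.65 ± 0.571 to 40.7 ± 1.57 CPM (4.62 ± 0.15, adjusted p = 3.64e-17). NF-kB targets fell in 23 and rose in 3 of 28 cases (median -0.66, adjusted p = 3.85e-05, and 0.0422 with an estimated correlation), among them Bcl3 by 1.94, Tnfaip3 by 1.26, Nfkb1 by 1.02 and Nfkbia by 0.35. Interferon response genes fell in 35 and rose in 5 of 41 cases (median -1.32, adjusted p = 1.45e-09, and 0.0187 with an estimated correlation), and 36 fell and 5 rose adjusted over the list alone. The interferon regulator Irf7 fell by 2.03, whereas Slfn1 rose by 1.53. Heat shock genes fell in 10 and rose in 2 of 16 cases (median -0.30), with Hsp90ab1 down by 0.99 and Dnajb1 by 1.08. Their camera adjusted p was 0.00205, and 0.149 with an estimated correlation. T cell receptor complex genes fell in 14 and rose in 7 of 23 cases (median -0.29), with Cd6 down by 1.39, Thy1 by 1.06 and Cd4 by 0.59. The camera adjusted p of this list was 0.00127, and 0.0422 with an estimated correlation.

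Targets of common gamma chain cytokines through STAT5 rose in 11 and fell in 2 of 16 cases (median 0.92, adjusted p = 0.000501, and 0.179 with an estimated correlation). Bcl2 rose from 223 ± 5.94 to 923 ± 12.3 CPM (2.05 ± 0.03, adjusted p = 1e-23), the kinase gene Pim1 by 2.07 and the receptor gene Il4ra by 1.06. Sterol synthesis genes rose in 16 and fell in 3 of 24 cases (median 0.59, adjusted p = 6.04e-05, and 0.0312 with an estimated correlation), and 17 rose adjusted over the list alone. Acat2 rose by 2.02, the sterol sensor gene Insig1 by 1.48, Stard4 by 1.40 and Msmo1 by 1.24. Respiratory chain genes rose in 24 and fell in 4 of 37 cases (median 0.35, adjusted p = 0.000502, and 0.0353 with an estimated correlation) and mitochondrially encoded messengers in 10 and 0 of 13 (median 0.40, adjusted p = 3.85e-05, and 0.211 with an estimated correlation). With the GC and length trend removed these 2 lists were no longer called, at adjusted p = 0.0869 and 0.403, the second with a median of 0.05, 6 genes higher and 4 lower. Of 81 ribosomal protein genes 77 rose and 3 fell (median 0.59, or 0.35 with the trend removed).

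**Figure D4:**
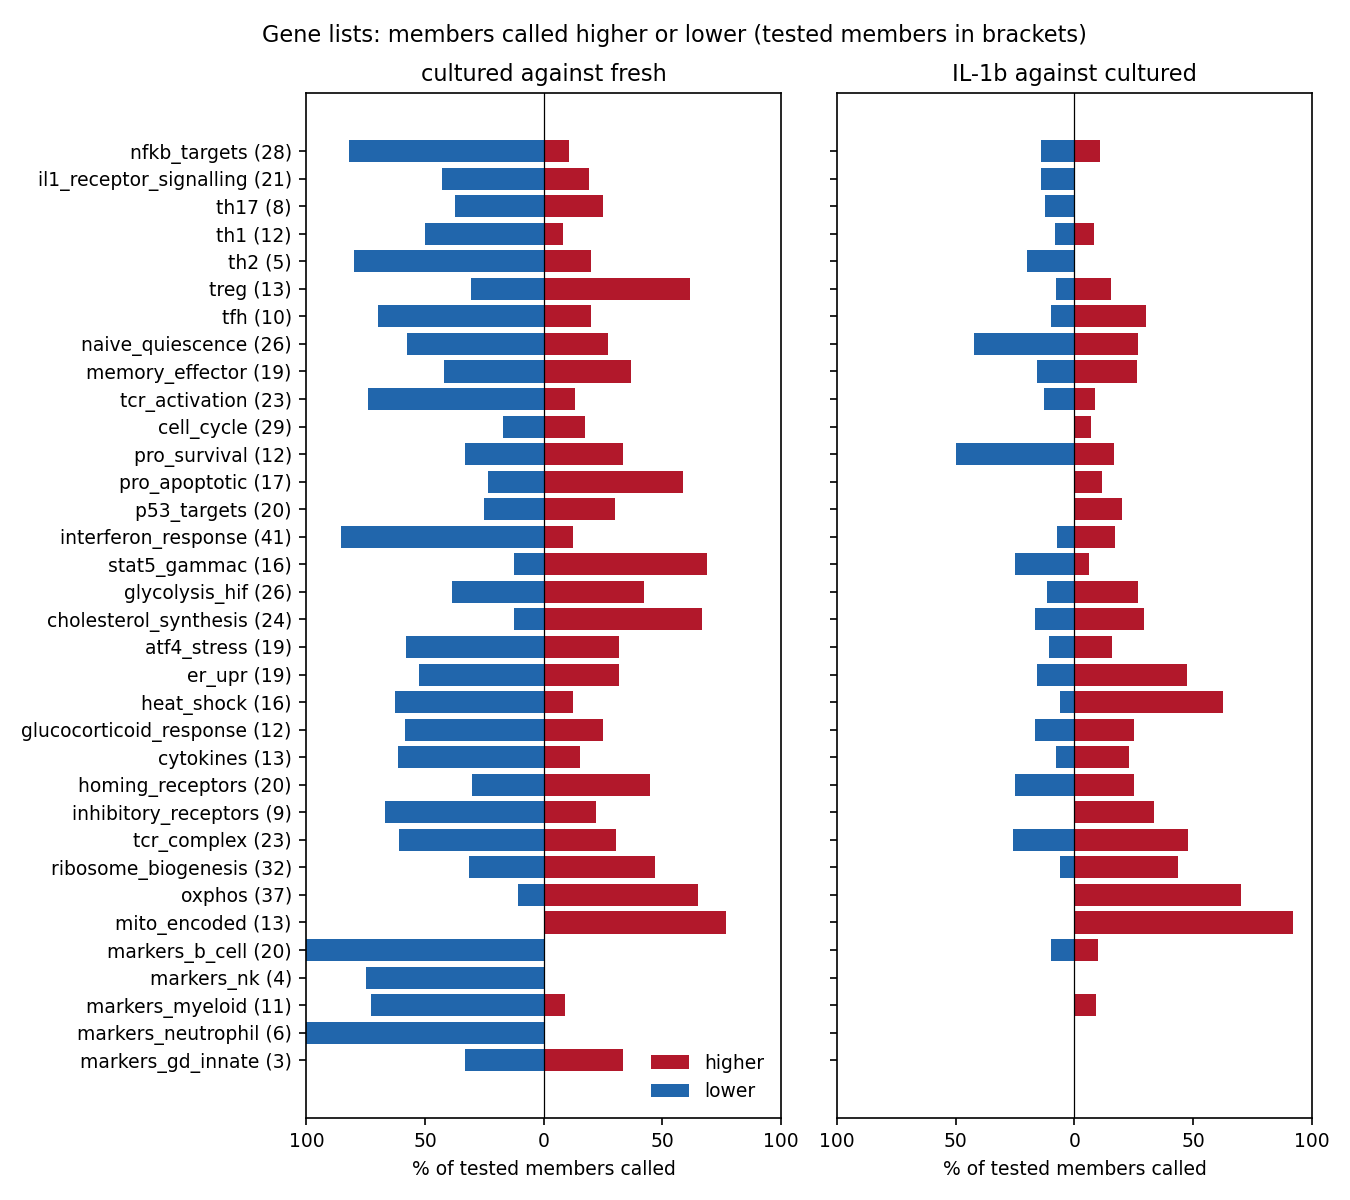
Bars give the percentage of the tested members of each gene list that were called higher (red) or lower (blue) under TMM scaling in cultured against fresh cells and in IL-1b-treated against cultured cells, with the number of tested members in brackets. All 20 B cell markers were lower after culture. In IL-1b-treated against cultured cells the medians of respiratory chain, ribosome assembly and heat shock genes turn negative on the TPM scale, at -0.06, -0.24 and -0.08.

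Naive T cell genes fell in 15 and rose in 7 of 26 cases (adjusted p = 0.0561, and 0.0495 or 0.0460 without fresh replicate 1 or 2). Ccr7 rose by 0.28, while Tcf7 fell from 1575 to 953 CPM, the naive state regulator Foxo1 from 494 to 175 CPM, Igfbp4 by 2.67 and the interleukin-7 receptor gene Il7r by 0.16. Regulatory T cell genes rose in 8 and fell in 4 of 13 cases (adjusted p = 0.0605), with Ctla4 up by 3.16, Tnfrsf18 by 2.69, Tnfrsf4 by 3.15 and Foxp3 by 1.11, which was not called without cultured replicate 1 (adjusted p = 0.0557). Th1 genes rose in 1 and fell in 6 of 12 cases, Th2 genes in 1 and 4 of 5 with Gata3 down by 1.42, Th17 genes in 2 and 3 of 8, and follicular helper genes in 2 and 7 of 10 with Bcl6 down by 2.81. Memory and effector genes rose in 7 and fell in 8 of 19 cases, and Cd44 fell from 20.2 to 3.28 CPM. The Th1 regulator Tbx21 had 26 counts in fresh, 2 in cultured and 1 in IL-1b-treated cells. Pro-apoptotic genes rose in 10 and fell in 4 of 17 cases, including Bcl2l11 by 0.96, survival genes in 4 and 4 of 12, p53 targets in 6 and 5 of 20 with Sesn1 up by 1.45, and ATF4 stress genes in 6 and 11 of 19 with Trib3 up by 2.96 and Ddit4 down by 3.03. Proliferation genes rose in 5 and fell in 5 of 29 cases, glycolysis genes in 11 and 10 of 26, ribosome assembly genes in 15 and 10 of 32, endoplasmic reticulum chaperones in 6 and 10 of 19 and glucocorticoid response genes in 3 and 7 of 12. IL-1 receptor family genes rose in 4 and fell in 9 of 21 cases with Il18r1 down by 0.50, secreted cytokines in 2 and 8 of 13, homing receptors in 9 and 6 of 20 and inhibitory receptors in 2 and 6 of 9. After removal of the GC and length trend proliferation genes rose in 6 and fell in 1 case and glycolysis genes in 13 and 5. The Th1 and myeloid marker lists were then called lower, both at adjusted p = 0.0399, or 0.149 with an estimated correlation.

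All 20 B cell markers fell (median -4.00, adjusted p = 4.1e-07, and 0.197 with an estimated correlation). The MHC class II chaperone gene Cd74 fell from 81.6 ± 12.5 to 4.32 ± 0.691 CPM, H2-Aa and H2-Ab1 by 4.76 and 4.61, and the immunoglobulin gene Ighm less, from 375 to 187 CPM. All 6 neutrophil markers tested fell, with a median of -6.96, or -5.46 with genes at 0 set to their bound. The camera adjusted p was 0.0105, and 0.315 with an estimated correlation. Only these 6 of 12 listed neutrophil markers passed the expression filter. A gene that passes it through its fresh level alone can only fall, so the filter partly sets this count and median. The 11 of 20 myeloid and 4 of 11 NK markers tested may share this limit. The receptor gene Cxcr2 went from 244 counts to 1, a ratio of 210 (exact 95% counting interval 37.4 to 8330). Myeloid markers fell in 8 and rose in 1 of 11 cases (adjusted p = 0.0733), with Lyz2 down by 6.57 and Cst3 up by 0.83, and NK markers fell in 3 of 4 with the perforin gene Prf1 down by 2.16. The CD8 T cell genes Cd8a and Cd8b1 rose by 1.16 and 1.10. Among gamma delta and innate-like T cell markers 1 of 3 rose, Tcrg-C1, whose call was lost without any of 3 libraries (adjusted p 0.0648 to 0.0861), and 1 fell, and the 1 erythroid marker tested fell.

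Comparing IL-1b-treated with fresh cells joins the culture and the cytokine. Of the 11 lists called for culture alone 9 were called here, and ribosomal protein messengers were further from fresh cells. Nuclear-encoded respiratory chain messengers were further from fresh cells under TMM scaling, with a median of 0.62 against 0.35 for culture alone. On the TPM scale they were not, at -0.02 against 0.05. Of 13043 genes 8539 differed, 4287 higher and 4252 lower, with a median fold of 1.62 and with 1313 higher and 1250 lower by at least 2-fold. Replicates were separate in TPM values for 69.0% of genes, where chance gives 10% and a shift of the median gene can add to it. Library size scaling gave 3408 higher and 5281 lower genes and log2(TPM + 1) values 1527 and 7113, with the median gene at -0.17 and -0.45, and at -0.50 on the TPM scale. With the GC and length trend removed 7966 genes differed, of which 6544 were among the 8539 in the same direction.

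Akr1c18 was at least 113-fold and Mpzl2 at least 47.0-fold higher than in fresh cells, the ratio for Dyrk4 was 221 (exact 95% counting interval 39.2 to 8780), Acvr1c rose by 7.29 and Exosc6 by 7.03. Hist1h4n was at least 74.4-fold lower, Cxcr2 at least 67.0-fold, the transcription factor gene Mef2c at least 54.9-fold and the growth factor receptor gene Csf3r at least 41.4-fold, and Hspa1a fell by 8.15. Respiratory chain genes rose in 30 and fell in 2 of 37 cases (median 0.62, or -0.02 on the TPM scale; adjusted p = 5.72e-07, and 0.0225 with an estimated correlation), and all 13 mitochondrially encoded messengers rose (median 0.93, adjusted p = 7.72e-08, and 0.202 with an estimated correlation). Ribosomal protein genes rose in 80 and fell in 1 of 81 cases (median 1.21). With the GC and length trend removed the medians of these 3 groups were 0.44, 0.50 and 0.73. Sterol synthesis genes rose in 17 and fell in 4 of 24 cases (median 0.63, adjusted p = 0.00103, and 0.0535 with an estimated correlation), and STAT5 targets in 11 and 3 of 16 (median 0.84, adjusted p = 0.0071, and 0.272 with an estimated correlation), with Il2ra up by 4.73 and Bcl2 by 1.84. On the TPM scale the medians of these 2 lists were 0.10 and 0.30. Those of mitochondrially encoded messengers and ribosomal protein genes were 0.32 and 0.62. Interferon response genes fell in 35 and rose in 5 of 41 cases (median -1.30, adjusted p = 6.64e-07, and 0.025 with an estimated correlation). Activation genes fell in 18 and rose in 4 of 23 cases (median -1.72, adjusted p = 4.16e-05, and 0.0281 with an estimated correlation), Jun by 5.01, and NF-kB targets fell in 21 and rose in 2 of 28 (median -0.83, adjusted p = 0.000272, and 0.0687 with an estimated correlation), Tnfaip3 by 1.22. Ctla4 rose by 3.44 and Npm1 by 1.49, Tcf7 fell by 0.96, and Il7r was not called at -0.06 (adjusted p = 0.0992). All 20 B cell markers fell (median -3.99, adjusted p = 8.74e-06, and 0.272 with an estimated correlation). Heat shock genes had 5 higher and 9 lower of 16, and T cell receptor complex genes 8 higher and 13 lower of 23. These lists were called in culture alone but not here (camera adjusted p = 0.231 and 0.0818). Both were called lower here as well with the GC and length trend removed (0.00683 and 0.000373), as were Th1 genes (0.0160). In that fit glycolysis and ribosome assembly genes were called higher (0.0232 and 0.0291). Each of these 5 was at 0.0968 or above with an estimated correlation. The 6 neutrophil markers that passed the filter fell with a median of -7.04, or -5.44 with bounds, a direction that the filter partly set. Their camera adjusted p of 0.0314 was 0.396 with an estimated correlation and 0.0607 without IL-1b-treated replicate 1.

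The relation of the cytokine's effect to that of culture was measured across the 13043 genes, where both comparisons share the cultured libraries with opposite sign and genes are not independent replicates. Pearson's r of the log2 fold changes was -0.03. In 20 simulations of unchanged groups its mean was -0.02, with a range of -0.05 to 0.02. These simulations drew fresh and IL-1b-treated counts around the observed mean of the real cultured libraries. The error of the cultured libraries therefore did not enter both simulated comparisons with opposite sign. The simulated values cannot show how far that error lowers r, rho or the covariance. Without cultured replicate 1, 2 or 3, Pearson's r was -0.142, -0.154 and -0.157, for which no simulation was run. Spearman's rho was 0.21, against a simulated mean of -0.00333. The covariance was -0.0157 against a simulated mean of -0.00101, a difference of -0.0147. Genes that rose in both steps numbered 1455, where independent lists would share 598, and 1090 fell in both, where independent lists would share 499.7. Another 191 genes rose with IL-1b after falling in culture and 287 fell after rising, against 588 and 508.2 for independent lists. The simulated overlaps were 0, which follows from simulating no changed gene, so they give no expectation for the observed ones. Chance values of the shared cultured libraries, which are too few to split, push genes in opposite directions in the 2 steps. With the GC and length trend removed, rho was 0.10, 1169 genes rose and 292 fell in both steps against 545.6 and 141.9 for independent lists, and 255 rose after falling and 134 fell after rising against 460.6 and 168.1. Among the 8824 genes above a log2 CPM of 3, r was 0.22 and rho 0.48.

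Transcripts of other cell types were followed as the summed TPM of their marker genes per library, and each comparison of 3 with 3 libraries used a two-sided exact permutation test whose smallest possible p is 0.1. B cell markers summed to 898 ± 94.7 TPM in fresh, 205 ± 5.88 in cultured and 187 ± 10.5 in IL-1b-treated cells. NK markers summed to 44.7 ± 3.02, 10.6 ± 0.594 and 9.44 ± 1.09 TPM in the same order, neutrophil markers to 38.2 ± 16.0, 0.62 ± 0.235 and 1.08 ± 1.17, and erythroid markers to 24.0 ± 14.5, 1.83 ± 1.92 and 1.12 ± 0.786. CD8 T cell markers went the other way, at 24.5 ± 0.922 TPM in fresh, 44.5 ± 4.90 in cultured and 40.3 ± 2.27 in IL-1b-treated cells. Myeloid markers summed to 85.4 ± 8.17, 85.6 ± 2.90 and 95.2 ± 6.28 TPM, a sum in which the rise of the abundant Cst3 stood against the fall of 8 of 11 tested markers after culture, gamma delta and innate-like T cell markers to 8.33 ± 1.34, 5.35 ± 0.307 and 5.11 ± 0.133, and stromal markers to 0.18, 0.0333 and 0.0233. Between cultured and fresh cells the exact permutation p was 0.9 for myeloid markers and 0.1 for each of the other 7 sums.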

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

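Removing the GC content and length trend was chosen after seeing the data. Where a value moved, the cause was not tested unless given. IL-1b-treated against cultured cells gave 2141 genes with the effective length offset, 2424 with the trend removed and 116 with at least 2-fold change, a stricter threshold by construction, which left 1654 for cultured against fresh and 2563 for IL-1b-treated against fresh. Leaving out single libraries gave 3024 to 3698, 7035 to 7835 and 8109 to 8539 genes, 4 to 5, 11 to 12 and 8 to 9 lists, and 395 to 411 of the 417 calls of named genes. The other alternatives kept gene counts within 1.5 times, but not always the same calls. Of the 3768 calls for IL-1b-treated against cultured cells, RLE size factors kept 3697 in the same direction. Library size alone kept 2922 of them and log2(TPM + 1) values 1880. An estimated correlation left 1, 6 and 3 lists, fry, which compares no list with other genes, called 19, 32 and 32, and removing the trend gave 7 lists for IL-1b-treated against cultured and 14 against fresh. The relation of the effects was -0.157 to -0.0207 without single libraries, -0.0891 with the trend removed and, by Spearman's rho, reversed to 0.215. With the trend removed the log2 fold change reversed for Il4ra (0.118), Stat6 (0.14) and Il6ra (0.0211) against cultured and for Stat6 (0.0645), Cdt1 (0.0315) and Vsir (0.493) against fresh cells. Of the 417 calls of named genes 367 held in every alternative run. Of 24 marker sums 11 moved by more than the replicate spread in CPM.

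The replicate block gave 3652, 7485 and 8454 genes and 4, 11 and 9 lists, and lost 6 of the 417 calls of named genes. Deviations of libraries with the same number correlated at -0.06 to 0.05 across genes, so no shared effect of a number was seen. This does not settle whether equal numbers pair the samples, which the labels leave open.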

Other observations

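The tests of the GC content and length trend, of the NF-kB targets, of scaling and of the B cell markers, and the ratio of falls within single fresh libraries, were chosen after the results were seen.

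The first pattern is the many small differences between IL-1b-treated and cultured cells. A trend on GC content and length, fitted to a random part of the genes, gave the sign of 90.5% of 1775 called genes among 4410 held out, all above a log2 CPM of 3, so it may account for much of the pattern among such genes. With the trend removed 52.6% of the calls kept their direction. The removal was incomplete, since genes of 13.17 to 678.8 bases kept a median of 0.13. It therefore cannot decide whether the trend is the whole cause. Without the 100 most counted genes, 3652 genes were called. TMM scaling already trims genes with extreme levels or changes, so this count could hardly move and decides nothing about a few abundant genes. NF-kB targets, with 3 higher and 4 lower and an adjusted p of 0.613, neither show nor exclude a response through Il1r1, for which all libraries had 0 counts; too few targets moved to decide. Whether length follows RNA quality, library preparation or a change in the cells cannot be told from groups that each hold their own libraries.

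The second pattern is the rise of ribosomal protein genes with IL-1b, with a median of 0.59 on the log2 scale. With the trend on GC content and length removed the median was 0.37 and 77 of 81 genes were still higher, so the trend may account for part of the rise. The removal was incomplete for short genes, since those of 13.17 to 678.8 bases kept a median of 0.13. It therefore cannot decide whether the trend is the whole cause. Genes picked as nearest in length, GC content and expression had a median of 0.38, but they were longer (637 against 422 bases) and less counted (a log2 CPM of 8.56 against 10.3), so that comparison, planned before its result was seen, decides nothing. The 35 genes with whole counts in most libraries had a median of 0.60, which argues against shared reads, and library size scaling gave 0.47. A higher content of these messengers in IL-1b-treated cells remains a hypothesis.

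The third pattern is the lower level of other cells' transcripts and of interferon response genes after culture. Of 20 B cell markers 19 fell at least 4-fold, but these falls raised the explanation that other cells were lost, and the remaining marker, Ighm, went only from 375 to 187 CPM. The interferon response list fell by 2.20 times as many CPM as the B cell, NK, myeloid and neutrophil marker lists together, and by 2.57, 2.07 and 2.02 times within the fresh libraries. The bound of 2 times set for that test assumed how many interferon transcripts the other cells hold, which no value here measures. Loss of other cells and lower expression per cell therefore cannot be told apart for the markers or for the interferon genes.

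Each comparison of 3 with 3 libraries allows 10 splits, too few for a share under 0.05. For gene counts with edgeR, 1 split (the real one itself) gave as many in each comparison, the real values being 3768, 7594 and 8539 and the highest other 0. For lists, the real 4, 11 and 9 stood beside a highest other of 2, 11 and 10, so that 1, 2 and 2 splits gave as many.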
